A study of Homo sapiens with 2 samples.

How the data were processed

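Each array had a deposited scanner table that held, per the file headers, intensity values from Agilent Feature Extraction 10.7.1.1 for 1 colour. The authors' processed signal in these tables is a background-subtracted linear intensity of one array, with no scaling between arrays. The raw mean spot intensity and the median local background of the deposited tables were used for an alternative background correction. The series value table deposited by the authors holds log2 values; how it was made is not given in the sources used here. Its columns had the same median, 4.59, and the same range, and across probes each correlated with log2 of its own array's processed signal, with a Pearson r of 0.9999 for the overexpression-labelled array and 0.9998 for control. It was therefore read as quantile-normalized log2 signal that was not centred per gene, and served as an alternative.

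Each array was its own group, taken from the sample labels: KIAA0101 overexpression (1 array) and control (1 array). With 1 array per group no model was fitted and no p-value or standard error was computed. Control spots were left out, as were outlier spots where other spots of the probe existed. Log2 of the processed signal was taken minus each array's 75th percentile, and spots of one probe were averaged. A probe counted as well above background where over 0.5 of its spots carried that mark. A gene's value was the median over its probes well above background on both arrays. A gene above background on one array alone was given as a bound against the higher of the dim probe's own level and the lowest level well above background on the dim array.

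Probes were named through a reference table of RefSeq accessions and symbols: 28174 probes matched by accession, 2618 by symbol and 620 by synonym, and 19187 kept the file's name. Of the 20220 genes measured on both arrays, 15027 had a current symbol. No genome was used, and the probe coordinates are those of the scanner table, whose build it does not name.

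The 44 gene lists, the alternatives, the 2-fold rule and the rule for named genes were fixed before the data were examined, except where stated. The rule took KIAA0101, then the 12 largest differences in each direction among unsaturated genes with a current symbol whose probes all had one sign and whose brighter level reached the median. It then took up to 5 bounds per direction and up to 4 genes per list by size. Genes on the Y chromosome and XIST were left out, and 1 gene that the rule took is not reported here. Lists needed at least 5 measured genes, and endothelial markers, with 4 of 14 measured, were not tested. A list's median was placed among 10000 random lists of equal size drawn from 20 bins of mean level with seed 1. The percentile describes these 2 arrays and is not a test.

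Alternatives were normexp background correction with an offset of 50, scaling to the median of measured probes, quantile normalization, loess on mean level with a span of 0.3, scaling to 8 spike-in probes, the brightest probe per gene, the deposited log2 table, no background filter, a level filter, spots marked saturated or non-uniform left out, 1.5-fold and 3-fold rules, and random lists not matched on level. Removal of a trend with probe GC content, probe start and level (polynomials of degree 3) was added after the data were seen, as was the use of the marked-spot alternative on gene lists. All 43 tested lists had GC and start values for 100% of their measured genes. Computations used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

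The steps were tested on simulated data built from the control array over 20220 genes with a noise SD of 0.1. All 50 genes simulated at 3-fold higher and all 50 at 3-fold lower passed the 2-fold rule, 0 of 50 and 0 of 50 at 1.5-fold did, and 0 of 20020 unchanged genes did. Of 200 random lists of 30 genes with no shift, 7 fell outside the central range, and all 50 lists shifted by 0.3 lay above it. The simulated noise was independent between probes, alike at all levels and without a trend with probe properties. The simulation thus checks the steps only. It does not give the rate of false 2-fold genes or lists on the real arrays. Among spots of one probe on one array, the median SD of log2 signal was 0.041 over 702 probes on the overexpression-labelled array and 0.039 over 685 on the control array, and 0.40% and 0.38% of spot pairs were 2-fold apart. Most of these probes were bright. Below the median level of measured genes the median SD was 0.108 (191 probes) and 0.112 (178 probes) on the same arrays. At or above that level it was 0.036 (511 probes) and 0.033 (507 probes).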

Results

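Gene expression was measured on 2 one-colour microarrays of cells labelled HepG2, the name of a line derived from a human liver tumour. One array carried RNA labelled as coming from a stable line overexpressing KIAA0101 and the other RNA labelled as control, so each group held 1 array. The series' design text speaks of 3 overexpressing and 3 control cells, and whether their RNA was pooled before hybridisation is not given in the sources used here. KIAA0101, now named PCLAF, encodes a small protein that binds the replication clamp PCNA and is used in DNA replication and repair. The comparison asks which signalling pathways differ when this gene is overexpressed.

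Both arrays had 62976 spots, of which 58717 were not controls and stood for 50599 probes. On the overexpression-labelled array 28912 probes (57.1%) were well above background, and on the control array 27685 (54.7%). No spot was saturated. The 75th percentile of the processed signal was 696 on the overexpression-labelled array and 508 on the control array. A total of 20220 genes were measured on both arrays, and across these genes, which are not independent replicates, the levels correlated with a Pearson r of 0.989. There were no replicates, so no test was possible and all differences describe these 2 arrays. The spread between spots of one probe covers error within an array only, and the number of arrays limits the precision of every value.

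The targeted gene was not higher on the array labelled overexpression. KIAA0101 was read by 1 probe, A_23_P117852, whose sequence is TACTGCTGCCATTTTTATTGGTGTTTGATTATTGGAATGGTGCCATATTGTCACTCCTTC. The file places it on chromosome 15 from 64657847 to 64657906, without naming the genome build, and 790 bases into the transcript. Its processed signal was 42986 ± 1031 (SD over 10 spots) on the overexpression-labelled array and 39998 ± 1365 (SD over 10 spots) on the control array. After each array was scaled to its 75th percentile, the log2 level was 5.95 and 6.30, a log2 difference of -0.35 (SD over spots 0.03). Relative to the median gene, which itself lay at -0.16, the difference was -0.19, at percentile 31.5 of all measured genes. After quantile normalization the difference was 0.00, which was 0.04 relative to the median gene, so its side of the median gene depended on the normalization. Scaling to the spike-in spots gave 0.57, but it shifts all genes alike and left the gene at -0.19 relative to the median gene. The encoded protein is short, which would put a probe this far into the transcript in the 3′ untranslated region, although the file does not annotate that. Which part of the gene the construct carried is not given in the sources used here, so a transgene without this region would go unread and the probe settles neither label. For this reason directions below are given as higher or lower on the overexpression-labelled array.

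The largest measured differences included enzymes of sterol synthesis among the higher genes and stress-response and histone genes among the lower ones. Of the 20220 genes, 217 were at least 2-fold higher on the overexpression-labelled array and 472 at least 2-fold lower, 3.41% in all. The share of higher genes in that total was 31.5% with this scaling, 21.5% (37 higher and 135 lower) with another background correction and 49.8% (313 and 315) with quantile normalization. It was 55.9% (350 and 276) after loess and 99.5% (6044 and 32) with scaling to the spike-in spots, under which the median gene lay at 0.76. The balance between higher and lower genes was therefore set by the scaling, and gene lists are given below relative to the median gene.

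The 12 genes with the largest higher values by the naming rule began with SAA1, an acute-phase protein, at a log2 difference of 2.44, and ZDHHC11, a palmitoyltransferase, at 1.90. SERPINB5, a serpin of epithelial cells, followed at 1.74. Sterol synthesis contributed HMGCS1 (1.72), IDI1 (1.61) and SQLE (1.39). Also among them were CA9, a carbonic anhydrase induced by hypoxia, at 1.65, the deubiquitinase USP9X at 1.64, the collagen gene COL1A1 at 1.54, the chaperone HSPA1A at 1.48 and the amylase AMY1C at 1.42. USP9X was at 0.94 once a trend with probe properties, described below, was removed. Measured probes numbered 3 for ZDHHC11, 2 for AMY1C and 1 for each other gene of the 12. With 1 probe the rule that all probes have one sign is met by default.

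The 12 genes with the largest lower values began with GKN1, a gastric secreted protein, at -2.22 and CHAC1, a glutathione-degrading enzyme induced by ATF4, at -2.17. They went on with the stress gene GADD45B at -1.85, STXBP6 at -1.81, the protease inhibitor SPINK6 at -1.80 and the matricellular gene CCN1 at -1.72. The replication-dependent histones H3C15 (-1.67), H2AC16 (-1.47) and H2AC8 (-1.43) were among them, as were the keratin KRT34 (-1.64), PRPS1L1 (-1.57) and the galectin LGALS9C (-1.49). CHAC1 and STXBP6 had 2 measured probes each and every other gene of the 12 had 1. SAA1, HSPA1A, AMY1C, LGALS9C and the histones have near-identical copies that a probe can also read, so the gene behind those values is uncertain. Other genes of the 24 may have such copies too, so this list may be incomplete. A further 133 genes were above background on the overexpression-labelled array alone, with a bound of at least 2-fold, and 312 on the control array alone. None of them was bright enough to be named under the rule. Without the 2-fold cut the counts were 1368 on the overexpression-labelled array alone and 576 on the control array alone. Which array had more such genes thus depended on the cut.

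Of 44 gene lists, 43 had enough measured genes. Of these, 17 had a median outside the central 95% of 10000 random lists matched on level. The count for lists of genes that vary independently would be 2.15. Genes of one list can vary together and some lists share genes, so the excess over 2.15 is not a test. Of the 17 lists, 15 were higher and 2 lower. ATF4 targets, replication-dependent histones, cholesterol biosynthesis, heat shock proteins and mitosis genes were the 5 that stood apart in the main setting and under the 10 alternatives run on lists that could move one. The other 2 alternatives shift all genes alike and cannot. The 10 are not independent checks. The deposited table was read as quantile-normalized and nearly repeats that setting, and leaving out marked spots did not change the counts of 2-fold genes.

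**Figure D1:**
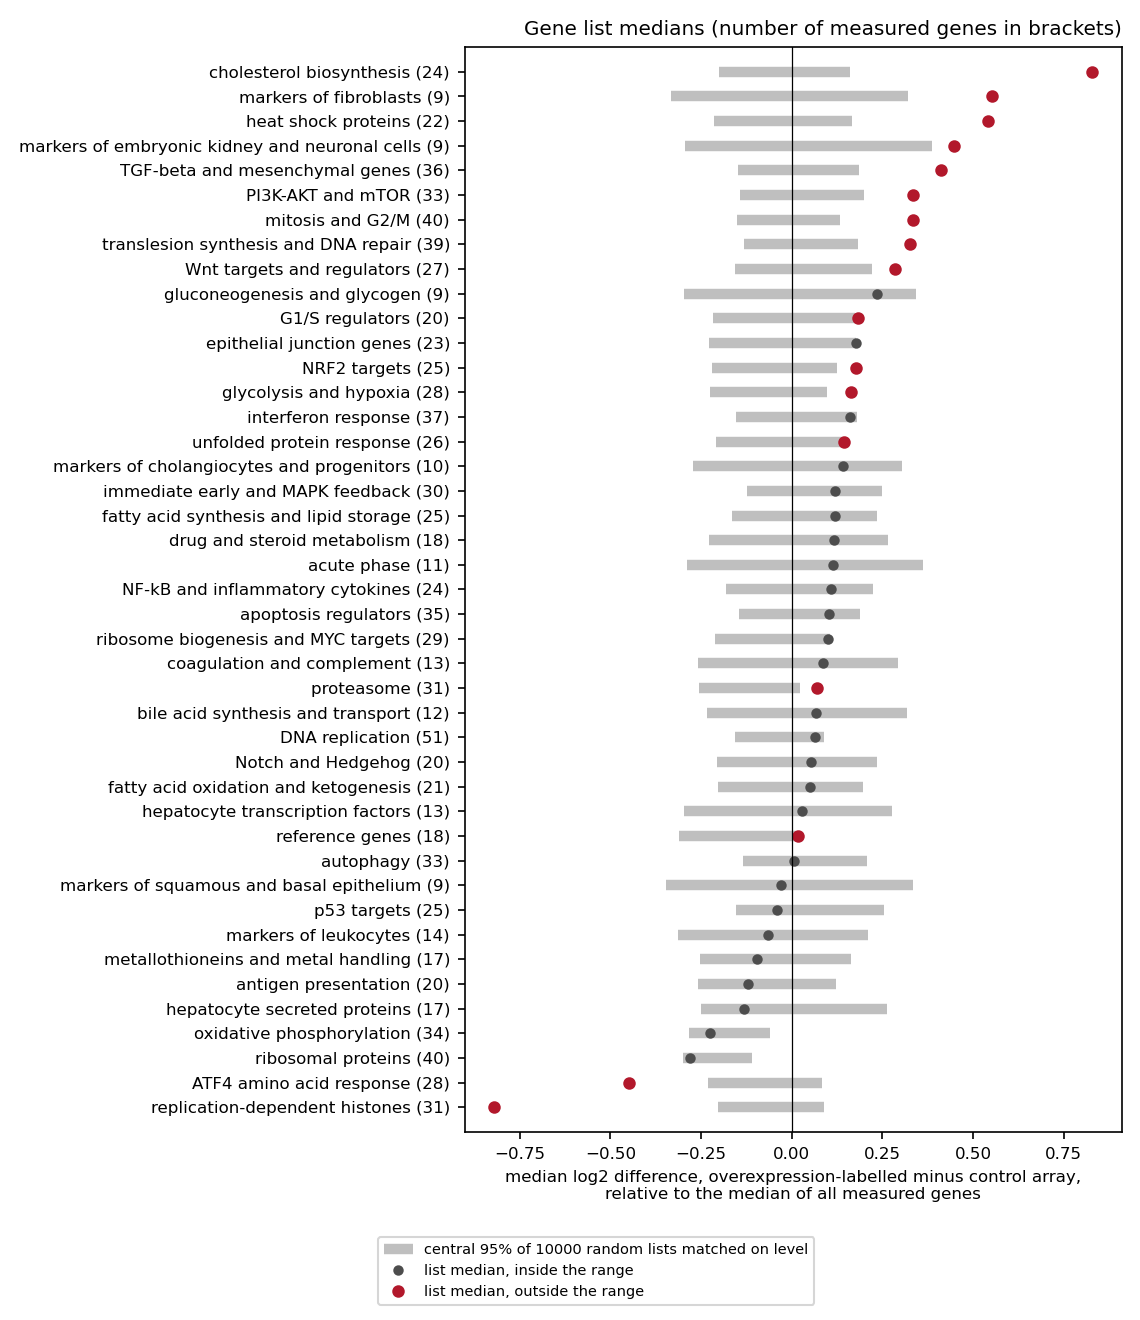
Median log2 difference of each of 43 gene lists, overexpression-labelled minus control array, relative to the median of all measured genes (horizontal axis), with one list per line. Grey bars give the central 95% of 10000 random lists matched on level, red points the 17 lists outside it and dark points the 26 inside; cholesterol biosynthesis lies at 0.83 and replication-dependent histones at -0.82.

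Genes of cholesterol biosynthesis were higher as a group on the overexpression-labelled array. Their median lay 0.83 above the median gene, above all 10000 random lists, with 22 of the 24 measured genes above the median gene. At least 2-fold higher were 7, and none was 2-fold lower. Besides the enzymes already named, MSMO1, a sterol demethylase, had a log2 difference of 1.70. Heat shock proteins lay 0.54 above the median gene, with 21 of 22 above it and 3 at least 2-fold higher. These were HSPA1A at 1.48, HSPA1B at 1.39 and HSPH1 at 1.12. Glycolysis and hypoxia genes had a median 0.16 above the median gene (percentile 99.6 of random lists), with 19 of 28 above it and 9 below. The 3 that were 2-fold higher were CA9 at 1.65, the glycolytic regulator PFKFB4 at 1.38 and the histone demethylase KDM3A at 1.35. Members on the lower side included ADM at -0.69, ANKRD37 at -0.46 and VEGFA at -0.44. NRF2 targets lay 0.18 above (percentile 99.3), with 1 of 25 at least 2-fold higher, the malic enzyme ME1 with a 2.14-fold difference, and GCLC, an enzyme of glutathione synthesis, at 0.97. Proteasome genes lay 0.07 above (percentile 99.4), and none of the 31 was 2-fold apart. With the probe trend removed, the proteasome median lay 0.27 above the median gene and that of glycolysis and hypoxia 0.25 above. These 3 lists came inside the random range when random lists were not matched on level, at percentile 75.7 for proteasome, 94.5 for glycolysis and hypoxia and 94.6 for NRF2 targets, which lay at 81.9 without a background filter.

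Mitosis genes were higher as a group, and genes of DNA replication were not set apart. The median of the 40 mitosis genes lay 0.33 above the median gene, above all random lists, with 34 above it. KIF11, a spindle motor, was at 1.06, the single member past 2-fold, with the proliferation marker MKI67 at 0.92 and TOP2A at 0.70. The 51 replication genes, among which KIAA0101 acts, lay 0.06 above the median gene (percentile 94.1), and none was 2-fold apart; with the brightest probe of each gene the list lay above the random range, at percentile 98.7. RFC3 was at 0.93, POLA1 at 0.91 and TK1 at -0.67. Regulators of G1/S lay 0.18 above (percentile 97.8), with none of 20 past 2-fold, CCNE2 at 0.77 and MYC at -0.56. Translesion synthesis and DNA repair genes lay 0.33 above (percentile 99.99), with none of 39 past 2-fold, CLSPN at 0.69, the checkpoint kinase ATR at 0.59 and ERCC1 at -0.67. Once the trend with probe properties was removed, the repair genes were at percentile 86.7 and G1/S regulators at percentile 88.1, both inside the random range, as were G1/S regulators under 6 alternatives in all, while mitosis genes stayed above all random lists. Targets of p53 lay at percentile 22.7, and at 0.27, below the random range, among genes at or above the median level, with 3 of 25 at least 2-fold higher and 2 lower. They went both ways, with TIGAR at 1.20 and BTG2 at 1.07 against SESN2 at -1.26 and GADD45A at -1.14.

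Targets of ATF4, the transcription factor of the amino acid response, and replication-dependent histones were lower on the overexpression-labelled array, each below all 10000 random lists. The ATF4 median lay at -0.45 relative to the median gene, with 23 of 28 genes below it and 6 at least 2-fold lower. CHAC1 was at -2.17, DDIT3 at -1.38, SESN2 at -1.26 and the mitochondrial enzyme PCK2 at -1.20. The unfolded protein response list, which shares 1 measured gene with it, lay 0.14 above the median gene (percentile 97.6). Its members past 2-fold, DDIT3 and PPP1R15A (-1.02), were both lower, so its largest differences ran against its median, and it came inside the random range under 9 alternatives, with the probe trend removed at percentile 92.7. The histone median lay at -0.82, with 28 of 31 genes below the median gene and 14 at least 2-fold lower. These included H3C7 at -1.27, H3C10 at -1.26 and H2AC17 at -1.25. The H2B genes ranged from -0.73 (H2BC11) to 0.004 (H2BC12), so none of them was 2-fold lower, and H3C1 was at 0.03. After removal of the probe trend the histone median was -0.46 and the ATF4 median also -0.46, both still below all random lists. With the trend removed, H3C1 (0.45), H2BC14 (0.18) and H2BC5 (0.03) were not lower, while H2BC11 (-0.52) and H2BC3 (-0.37) were.

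**Figure D2:**
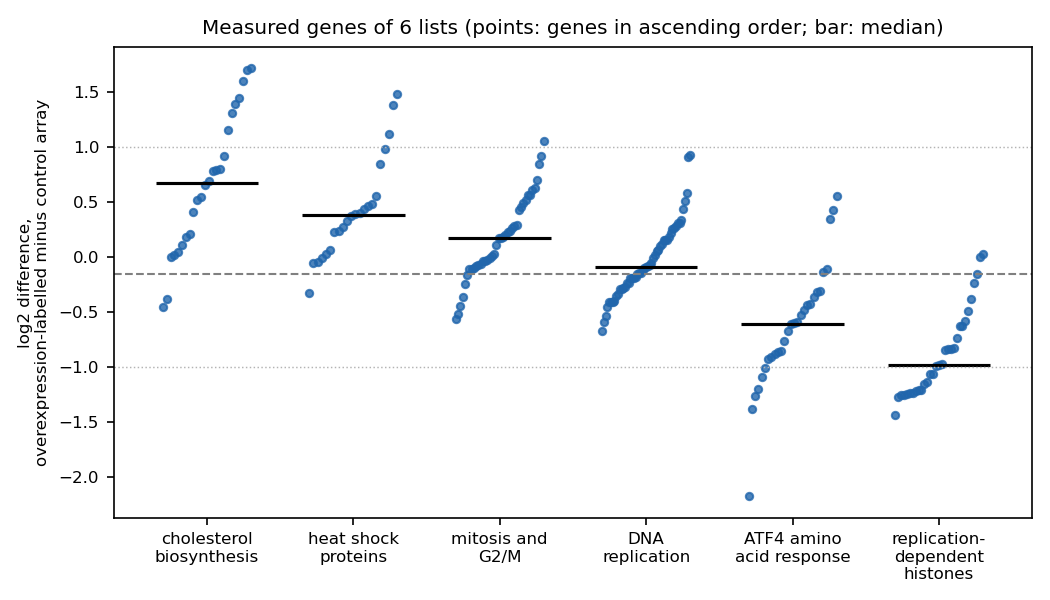
Log2 difference of each measured gene, overexpression-labelled minus control array (vertical axis), in 6 gene lists, with genes in ascending order within a list. Bars give list medians, the dashed line the median of all measured genes at -0.16 and the dotted lines a 2-fold difference; 7 genes of cholesterol biosynthesis lie above the upper dotted line and 14 histone genes below the lower one.

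Among signalling lists, PI3K-AKT, Wnt and TGF-beta genes had medians above the random range, and autophagy and apoptosis genes did not. PI3K-AKT and mTOR genes lay 0.33 above the median gene (percentile 99.9), with 29 of 33 above it and 1 past 2-fold, IGF2 at 1.02. IGF2 was dim and read by 1 probe. Its level was -3.91 on the overexpression-labelled array and -4.93 on control, against a median level of -0.98 for measured genes. The translation repressor EIF4EBP1 was at -0.78. Wnt targets and regulators lay 0.28 above (percentile 99.5). WNT11 at 1.11 and the receptor gene FZD5 at 1.02 were 2-fold higher, and the Wnt inhibitor DKK1 at -1.11 was 2-fold lower. WNT11 (levels -3.22 and -4.33 on the same arrays) and FZD5 (-1.55 and -2.57) also lay below the median level, with 1 probe each. After the probe trend was removed, PI3K-AKT genes lay at percentile 78.0 and Wnt genes at percentile 80.2, inside the random range. TGF-beta and mesenchymal genes lay 0.41 above, beyond all random lists, and 0.17 above at percentile 99.3 with the trend removed, with 2 of 36 at least 2-fold higher (COL1A1 at 1.54 and SMAD2 at 1.02) and 2 lower (CCN1 at -1.72 and CCN2 at -1.22). Without a background filter this list was at percentile 95.2, inside the random range, and with the brightest probe of each gene Wnt genes were at 94.2. Autophagy genes were at percentile 38.5, with 1 member of 33 past 2-fold, GABARAPL1, which was lower. Apoptosis regulators were at percentile 83.7, with HRK at -1.09 as the 1 of 35. Notch and Hedgehog genes were at percentile 68.3 with NOTCH3 at 1.19, interferon genes at percentile 95.8 with IFI44 at 1.13, inflammatory cytokines at percentile 81.3 with PTGS2 at 1.04 and immediate early genes at percentile 73.3 with NR4A2 at 1.26. Several of these medians turned from above to below the median gene with the probe trend removed: immediate early genes (0.12 and -0.11, percentile 7.15), inflammatory cytokines (0.11 and -0.04, percentile 28.0), and Notch and Hedgehog genes (0.05 and -0.09, percentile 16.7).

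Many transcripts typical of liver cells were not well above background on either array. Of 32 secreted hepatocyte proteins on the array, 15 were above background on neither array, as were 23 of 38 coagulation and complement genes. Albumin (ALB) had a processed signal of 2.86 and 6.36 on the overexpression-labelled and control arrays, and alpha-fetoprotein (AFP) 2.70 and 2.71, none of them well above background. The same held for APOB, TTR, TF and the fibrinogen genes FGA, FGB and FGG. KRT7, a keratin of bile duct and other simple epithelia, had a signal of 161334 and 184938 on the same arrays, and VIM, a filament protein of mesenchymal cells, 82434 and 83868, all well above background. These genes were chosen after their values were seen. All 18 reference genes and all 51 replication genes were above background on both arrays. Among the hepatocyte genes that were measured, SERPINA1 was at -1.23 and APOA1 at -0.90, and the 17 secreted proteins lay at percentile 16.7. Their median turned from -0.13 to 0.06 relative to the median gene with the probe trend removed (percentile 72.5). Markers of fibroblasts lay 0.55 above the median gene (percentile 99.9, 9 measured genes, 3 shared with the TGF-beta list), with 7 of the 9 above it, COL1A1 at 1.54 and DCN at 0.63, against PDGFRB at -0.56 and S100A4 at -0.41. The fibroblast median was 0.34 above (percentile 99.4) with the probe trend removed and inside the random range, at percentile 63.9, without a background filter. Markers of embryonic kidney and neuronal cells lay 0.45 above (percentile 98.9, 9 measured genes), and at percentile 96.8, inside the random range, with the probe trend removed. The 3 other alternatives that did so gave 95.1 with a level filter, 96.6 without a background filter and 87.3 with normexp.

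Differences between the arrays followed properties of the probes. The median log2 difference was 0.13 for probes with up to 35% GC and -0.47 for those above 55%, with a Spearman rho of -0.38 across probes. It was -0.34 for probes starting within 500 bases of the transcript start and 0.29 for those beyond 4500, with a rho of 0.40. Together with level, these properties held 23.7% of the variance across 26012 probes, which are not independent replicates. Reference genes lay at percentile 97.8 of random lists, 0.02 above the median gene, and came inside the random range under 4 alternatives, at percentile 88.7 once the trend was removed and at 55.5 without matching on level. For 111 genes with a second probe and a brightest probe at least 2-fold apart, the second was also 2-fold apart in the same direction in 28 (25.2%) and on the same side of the median gene in 89 (80.2%).

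**Figure D3:**
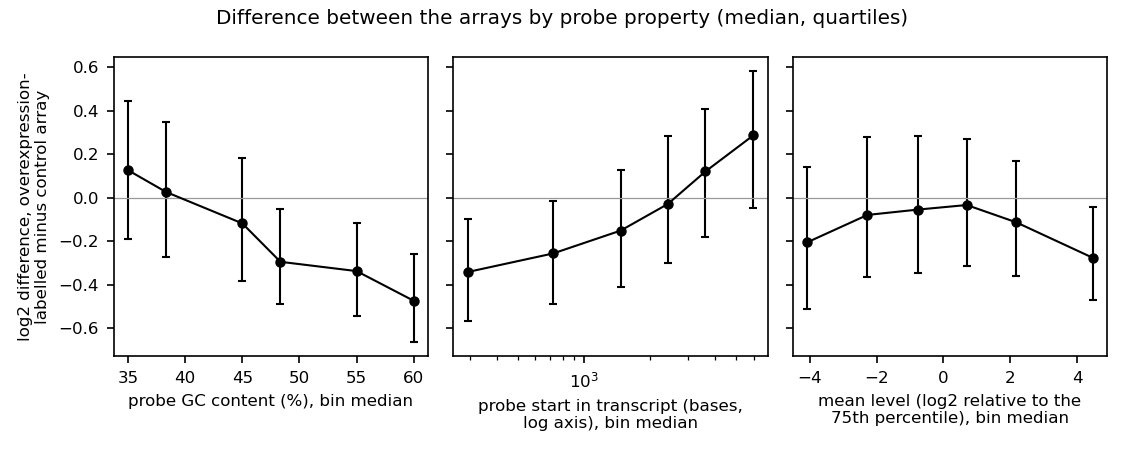
Median log2 difference of probes, overexpression-labelled minus control array (vertical axis), by probe GC content in percent, by probe start in the transcript in bases on a log axis, and by mean level. Points are bin medians and bars the quartiles; medians go from 0.13 to -0.47 with GC and from -0.34 to 0.29 with probe start.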

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

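No paired analysis was possible because each group had 1 array, and no array could be left out. Removal of the probe trend, and leaving out marked spots for the gene lists, were chosen after the data were seen; the other alternatives were planned. The cause of each move was not tested unless stated. The KIAA0101 difference, -0.35, was -0.30 with normexp, 0.00 with quantile normalization and in the deposited table, -0.018 with loess, -0.20 with the trend removed and 0.57 with spike-in scaling, which shifts all genes alike. Relative to the median gene it was -0.19 in the main setting and with spike-in scaling, and between -0.21 and 0.04 over all settings. Genes at least 2-fold higher, 217, were 37 with normexp, 350 with loess, 6044 with spike-in scaling and 127 with the trend removed. They were 954 without a background filter, which adds genes, 46 at or above the median level, which removes them, 1262 at 1.5-fold and 27 at 3-fold. Genes at least 2-fold lower, 472, were 135 with normexp, 276 with loess and 32 with spike-in scaling, and 2371, 112, 2719 and 64 in the same order of filters and fold rules. Bounds of at least 2-fold on one array alone were 133 higher and 312 lower. With normexp they were 8 and 64, with loess 224 and 176 and with spike-in scaling 615 and 100, and the deposited table gave 202 higher. Between 13 and 18 lists lay outside the random range under the 13 settings, the main one included, of which 2 scalings shift all genes alike and cannot move a list. Of the 17 lists, 10 stayed outside with the trend removed, 11 without a background filter, 11 without matching on level and 13 with the brightest probe, and 3 others entered with the trend removed. None of the 24 genes named for size turned direction, but they were picked for large differences in these same data. Their keeping direction therefore says little about how stable the values are. With spike-in scaling 10 of them were no longer 2-fold apart, and 1 each with normexp and with the trend removed. The spike-in median was -0.46 over 8 probes before scaling, against 0.45 for the 75th percentile of the arrays, so the scalings cannot be chosen between from these arrays. Background limits the range: 1368 genes were above it on the overexpression-labelled array alone and 576 on the control array alone.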

Other observations

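In the main setting, ribosomal protein genes and oxidative phosphorylation genes lay below the median gene without leaving the range of random lists matched on level. The 40 ribosomal genes had a median of -0.28 relative to the median gene (percentile 7.07), and the 34 oxidative phosphorylation genes one of -0.23 (percentile 22.8); none in either list was 2-fold apart. With the probe trend removed both medians lay above the median gene, at 0.04 (percentile 88.7) for ribosomal genes and 0.006 (percentile 63.5) for oxidative phosphorylation. Without matching on level both lay below the random range, at percentile 0 and 0.32, as did ribosomal genes without a background filter, at 1.78. Genes of fatty acid synthesis were at percentile 82.4 with ME1 2.14-fold higher, fatty acid oxidation at percentile 73.4 with PDK4 at 1.02 and ACADS at -1.15, and drug and steroid metabolism at percentile 82.0 with UGT1A6 at 0.98. Metallothioneins and metal handling genes were at percentile 37.7 and at percentile 99.97 once the probe trend was removed. In all, 13 list medians changed sides of the median gene in this step, none of them of a list outside the random range in the main setting. Acute phase genes went from percentile 73.9 to percentile 98.7 and gluconeogenesis genes from percentile 91.5 to the 99th in the same step. Ribosome biogenesis genes were at percentile 96.8, epithelial junction genes at percentile 97.47, antigen presentation at percentile 33.0, bile acid genes at percentile 62.3, hepatocyte transcription factors at percentile 66.3 and coagulation and complement genes at percentile 72.8. Some of these lists left the random range under an alternative. Fatty acid synthesis was at 99.1 with the brightest probe, and drug and steroid metabolism at 98.9 with the level filter and 98.6 without a background filter. Ribosome biogenesis was at 98.2 and gluconeogenesis at 98.1 with normexp, and bile acid genes at 0.64 with the level filter. Epithelial junction genes were at 97.69 in the deposited table, 97.74 with marked spots left out, 97.97 with loess and 98.3 with quantile normalization. Markers of leukocytes were at percentile 51.2, of squamous epithelium at percentile 52.97 and of cholangiocytes at percentile 83.5.

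The tests of S phase, of transcripts without a poly(A) tail, of array brightness and of the cells' label were chosen only after the results were seen, and removal of the probe trend was added after the trend was seen.

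Several gene lists were set against the trend of differences with probe GC content, position and level. With the trend removed, cholesterol biosynthesis stayed at percentile 100 and mitosis at percentile 100, which argues against the trend as the whole cause of either. DNA repair genes moved to percentile 86.7 (median relative to the median gene 0.33 before and 0.08 after) and PI3K-AKT genes to percentile 78.0 (0.33 and 0.06), which is consistent with the trend as the source of both. Such a trend may come from RNA quality or labelling, which was not tested, and a biological difference that follows transcript length stays open. For cholesterol biosynthesis, a difference between the 2 cultures unrelated to the transgene cannot be told apart from one due to overexpression, since there was 1 array per group.

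The lower histone values were also set against the trend, and the list stayed at percentile 0 with it removed, although its median moved from -0.82 to -0.46. The drop was uneven, since the H2B genes ranged from -0.73 (H2BC11) to 0.004 (H2BC12) before the trend was removed. Fewer cells in S phase may lower histone transcripts. However, the DNA replication list lay at percentile 94.1, with 31 members above the median gene and 20 below it. This was left as not settling the question because 94.1 lay inside the random range, whose edges were the test's bounds. The upper bound was first set at the middle of the random lists, which would have counted 94.1 against fewer S-phase cells. It was moved to the edge of the random range after the value was seen. With the brightest probe of each gene the list lay at percentile 98.7, past that edge, and with the probe trend removed at 65.8, inside the range. The outcome thus depended on the bound and on the setting. Mitosis genes at percentile 100, with 34 of 40 above the median gene, run against fewer cycling cells in general, whereas the call of G1/S regulators at 97.8 was lost under 6 alternatives and is not used here. A shift of cells from S phase to other stages would not need to lower mitosis genes, so it stays open. Most of these histone transcripts lack a poly(A) tail. In 3 of 3 list genes with a probe starting within 500 bases and one beyond 600, the nearer probe was the lower (H2AC6 -1.31 and 0.05, H2BC12 -0.28 and 0.29, H2BC21 -0.74 and 0.45). Nearer probes were lower on these arrays in general, and with the trend removed the nearer minus farther difference shrank from -1.36 to -1.10, from -0.56 to -0.23 and from -1.19 to -0.80. The nearer probe itself was then at -1.12 for H2AC6 and -0.46 for H2BC21, but at 0.15 for H2BC12, which was thus not lower. The differences that remain could come from different recovery of transcripts without a poly(A) tail. Regulation of the short transcripts alone cannot be told apart from it.

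Hepatocyte transcripts at background on both arrays stand out for cells labelled HepG2, a line known to secrete albumin, alpha-fetoprotein and apolipoproteins. Arrays too dim to read them are argued against by the reference genes, of which 18 of 18 were above background on both arrays. Cells other than the labelled line could leave 15 of 32 secreted proteins above background on neither array. So could cells of that line that had lost these transcripts. Several of the secreted proteins that were measured were dim, so the count of 15 does not mean that the rest were strongly expressed. KRT7 and VIM, well above background on both arrays, bear on the same question, but they were picked after their values were seen and no expression profile of the labelled line was used here, so it stays open. Both arrays shared the pattern.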
